A study of Mus musculus with 14 samples.

How the data were processed

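RNA sequencing libraries of mouse CD4 T cells were analysed from the deposited gene tables of 2 experiments. In the culture experiment, primary CD4 T cells from C57BL/6 spleen were left in medium (2 libraries), stimulated with antibodies to CD3 and CD28 (3 libraries) or stimulated with the same antibodies together with TRAIL, the death receptor ligand encoded by Tnfsf10 (3 libraries). The labels give the antibodies at 1 mg/ml and TRAIL at 10 ug/ml, and both doses are printed as labelled. In the mouse experiment, spleen CD4 T cells came from TRAIL-R floxed mice given vehicle (1 library), TRAIL-R floxed mice given TRAIL (3 libraries) and Lck-Cre TRAIL-R floxed mice given TRAIL (2 libraries). Groups and replicate numbers follow the sample titles. The bracketed name of Lck-Cre TRAIL replicate 1 carries no TRAIL tag, and the titles of both Lck-Cre libraries misspell TRAIL. The bracketed name of medium replicate 2 carries the number 3. The vehicle library is titled TRAIL-R floxed, but its bracketed name is B6_spleen, so its genotype may differ from that of the floxed libraries given TRAIL. All 8 culture libraries were sequenced on lane 3. The vehicle library, floxed TRAIL replicate 1 and Lck-Cre TRAIL replicate 1 were on lane 2, and the other mouse libraries were on lane 4. No label says that replicates were separate animals or cultures, so each p-value measures only the spread between libraries.

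The deposited expression values are in TPM, per the file headers of the culture table. The headers of the mouse table name only the libraries, and its unit was inferred: each deposited column of both tables sums to 1000000, as TPM values do. The authors' log2 fold changes stand beside them, per the file headers, under named comparisons in the culture table and with no comparison named in the mouse table. The deposited p-values and adjusted p-values come per the file headers from the authors' own tests, whose adjustment is not stated. The length column holds bases per gene, per the file headers. For the mouse experiment the authors also deposited over-representation tables with a count of listed genes in each set and p-values, and a gene set enrichment table with a normalized enrichment score, a set size, p-values and q-values, per the file headers. The submitters' notes name bcl2fastq, Trimmomatic 0.36, HISAT2 2.1.0, SAMtools 1.2, StringTie 2.1.4, DESeq2 1.26.0 and the build GRCm38.p6, without saying which step used which tool or how genes were filtered. The strand of read counting is not stated.

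The culture table lists 20875 genes, and 18855 are listed for the mouse experiment. Of the listed genes, 571 to 1287 were at 0 in each culture library and 0 were at 0 in any mouse library. Genes without reads in some mouse library may therefore have been left out before deposit, and could then not be tested here. Gene coordinates on GRCm38 were taken from the GENCODE annotation by Ensembl identifier and were found for 99.8% of the genes of each table. TPM times gene length was a whole multiple of 1 step in every library, with a largest deviation of 2.33e-10 from a whole number. Taking that step as 1 read, the libraries held 19.2 to 56.9 M reads, and 1 TPM at the median gene length stood for 20.4 to 67.4 reads. Depth limits the precision of genes near or below 1 TPM.

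The design written before the data were examined assumed read counts and named the edgeR quasi-likelihood test, which was not run because the deposited tables are in TPM. The design also named the test for that case, and it was used: limma 3.58.1 in R 4.3.3, with moderated statistics and a trend of the variance on the mean, on log2(TPM + 1), with all libraries of an experiment in 1 fit and 1 coefficient per group. Genes with a mean TPM of at least 1 over the libraries of an experiment were tested, 14035 in culture and 14176 in the mouse experiment. P-values were two-sided and adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. Each log2 fold change is on the log2(TPM + 1) scale, which understates the change of genes with low TPM. The residual degrees of freedom were 5 in culture and 3 in the mouse experiment. The vehicle group has 1 library, which was assumed to vary like the other groups. TPM values were not rescaled for the main results. Scaling by the median of ratios across genes was run as an alternative, and report values marked as scaled come from it.

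Gene lists were fixed before the data were examined: 21 lists of cell programmes (activation genes induced by the T cell receptor, T cell receptor signalling machinery, cell cycle, ribosome biogenesis and MYC targets, glycolysis, oxidative phosphorylation, sterol biosynthesis, Th1, Th2, Th17, Treg and Tfh programmes, naive and quiescent T cell genes, inhibitory receptors and anergy genes, death receptor and apoptosis genes, NF-kB targets, interferon response, migration and adhesion, endoplasmic reticulum (ER) stress and amino acid response, heat shock and p53 targets) and 9 lists of markers of other cells (B cells, plasma cells, macrophages and monocytes, neutrophils, dendritic cells, CD8 T and NK cells, erythroid cells and platelets, stromal and endothelial cells, mast cells and basophils). The stromal list had 2 measured members in culture and was not tested there, so 29 lists were tested in culture and 30 in the mouse experiment. Lists were tested with camera from limma on the same genes and fit, with a preset inter-gene correlation of 0.01, and adjusted over all lists of a comparison. Camera compares a list with all other genes. The same test with a correlation estimated per list was run as an alternative. Counts of members past the threshold were also adjusted over the list alone.

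The rule for named genes was fixed before the data were examined. In each comparison it takes, among genes past the threshold with an absolute log2 fold change of at least 1, a mean log2 value of at least 1 and no overlap between the groups' libraries, the 10 highest and 10 lowest fold changes, leaving out predicted genes, pseudogenes and antigen receptor segments. From each list it takes up to 4 members past the threshold with the largest fold changes. A fixed set of genes, among them Tnfrsf10b, Tnfsf10, Lck, Cd4, Il2ra, Ifng, Foxp3, Casp8, Cflar, Mki67 and Myc, is given whatever its test. Where fewer than 5 genes passed, the 5 with the smallest unadjusted p-values are given as values.

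The fits were tested on simulated data: negative binomial reads for the real genes, with the spread of the real libraries and 200 changed genes, turned into TPM. In culture, 93.9% of genes changed 4-fold and 65.7% to 82.1% of those changed 2-fold were recovered, with at most 9 unchanged genes called. The simulated changes went in random directions. These rates therefore do not cover data in which most genes and the median gene shift, as in the real culture libraries. In the mouse experiment, 0 changed genes were recovered in the comparisons with the vehicle library, and 23 of 66 genes changed 4-fold were recovered between Lck-Cre and floxed libraries with TRAIL.

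Changes with stimulation and with TRAIL were compared by their correlation and covariance across genes, beside 50 simulations with no group effect that shared the stimulated libraries in the same way. Alternatives tried were median-of-ratios scaling, no filter, pseudocounts of 0.1 and 0.5, a fit of only the compared groups, a minimum absolute log2 fold change of 1, a block for replicate number or lane, an estimated correlation in the list tests, 200 genes each way for the culture gene sets, and each library left out in turn. Voom weights on the recovered reads, lane 4 or lane 2 libraries alone, and some pairings of these with the list tests were added after seeing the data. The 14 deposited columns of z-scores were left out, since they restate the TPM values. Figures were drawn with matplotlib 3.10.9 and tables handled with pandas 2.3.3 in Python 3.11.15.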

Results

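Whole-transcriptome RNA was sequenced from mouse CD4 T cells in 14 libraries, 8 from culture and 6 from treated mice. The culture libraries came from spleen CD4 T cells of C57BL/6 mice held in medium (n = 2; 29.5 and 26.3 M reads), with antibodies to CD3 and CD28 (n = 3; 32.3, 32.3 and 27.6 M) or with the same antibodies and TRAIL (n = 3; 23, 26.5 and 31.0 M). The mouse libraries came from spleen CD4 T cells of TRAIL-R floxed mice given vehicle (n = 1; 56.9 M reads), TRAIL-R floxed mice given TRAIL (n = 3; 24.5, 24.7 and 24.3 M) and mice labelled Lck-Cre TRAIL-R floxed that were given TRAIL (n = 2; 40.1 and 19.2 M). Read numbers were recovered from the TPM values and gene lengths. Genes are given as mean TPM ± SD, and fold changes are on the log2(TPM + 1) scale, where the change of a gene with low TPM is understated.

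The first culture comparison asked which genes changed when CD4 T cells were stimulated through CD3 and CD28. Cells in medium (n = 2) expressed resting T cell genes such as Il7r and S1pr1, and stimulated cells (n = 3) expressed cytokine, cytotoxic and growth genes. Il21, a cytokine gene of helper T cells, rose from 0.176 ± 0.0894 to 433 ± 9.19 TPM (log2 fold change 8.53 ± 0.086 SE, adjusted p = 2.28e-09). Gzmb, which encodes granzyme B, rose from 13.3 ± 1.11 to 1567 ± 48.2 TPM (6.78, adjusted p = 1.19e-08). Il2ra, the gene of the high-affinity interleukin 2 receptor chain, rose from 76.6 ± 3.85 to 906 ± 123 TPM (3.54), and Myc from 128 ± 15.7 to 619 ± 40.3 TPM (2.27). Tbx21 rose from 5.11 ± 0.199 to 119 ± 7.47 TPM (4.30) and Ifng from 2.13 ± 0.180 to 78.4 ± 18.2 TPM (4.64). Il7r fell from 774 ± 60.0 to 42.9 ± 5.69 TPM, S1pr1 from 468 ± 16.5 to 30.2 ± 5.81 TPM and Bcl6 from 54.6 ± 0.441 to 5.65 ± 1.01 TPM (-4.15, -3.92 and -3.08). Markers of other cells were present in medium and fell, so changes in the culture libraries cannot all be assigned to CD4 T cells. Lyz2 of myeloid cells fell from 747 ± 38.3 to 6.38 ± 1.27 TPM (-6.68, adjusted p = 3.30e-08) and Cd79a of B cells from 251 ± 3.31 to 20.8 ± 0.850 TPM (-3.53).

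The 10 largest rises were those of Il21, Gzmb, Crabp2, Cth, Lag3, Lif, Egln3, Il13, Ak4 and Ccr8. The 10 largest falls were those of Slc28a2b, Marco, Lyz2, Rapgef4, Tmem71, Fcmr, St8sia6, Rnf32, Gpnmb and BC106179. Lag3 rose from 7.53 ± 0.221 to 415 ± 9.10 TPM, Il13 from 0.289 ± 0.147 to 45.6 ± 3.34 TPM and Cd69 from 54.9 ± 3.13 to 480 ± 21.6 TPM. Foxp3 fell from 66.3 ± 0.236 to 28.1 ± 6.22 TPM and Cd4 from 682 ± 9.42 to 326 ± 57.9 TPM. Il2 rose from 1.14 ± 0.142 to 14.5 ± 6.86 TPM, Csf2 by a log2 fold change of 3.30, Il17a by 1.93, Gata3 by 1.63 and Tnf by 0.84. Lck and Casp8 fell, with log2 fold changes of -0.23 and -0.46. Il17f, Mki67 (44.8 ± 20.4 against 31.1 ± 0.322 TPM, adjusted p = 0.356) and Cflar (260 ± 46.7 against 270 ± 12.0 TPM) did not pass the test. Tnfrsf10b, the mouse TRAIL receptor gene, rose from 4.97 ± 0.238 to 9.10 ± 1.29 TPM (0.75, adjusted p = 5.73e-04). Tnfsf10, the gene of TRAIL itself, fell from 20.5 ± 0.636 to 8.77 ± 0.612 TPM (-1.14).

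Activation genes rose as a list: 35 of 40 rose, 2 fell and 3 did not pass, with a median log2 fold change of 2.09 (adjusted p = 1.48e-14, and adjusted p = 0.0285 with an estimated correlation). Ribosome biogenesis and MYC targets (28 of 30 up, 1 down, median 1.60) and ER stress and amino acid response genes (26 of 29 up, 2 down, median 1.37) also rose under both settings. They had adjusted p = 0.0181 and adjusted p = 0.0138 with an estimated correlation. Cell cycle genes (43 of 46 up, 0 down, median 1.59), glycolysis genes (17 of 20 up, 1 down, median 2.35) and sterol biosynthesis genes (19 of 22 up, 0 down, median 1.14) were higher, with adjusted p = 6.95e-17, 1.72e-09 and 4.41e-09. These had adjusted p = 0.0964, 0.0935 and 0.0935 with an estimated correlation. Oxidative phosphorylation (29 of 33 up, 0 down, median 0.78), Th2 (9 of 13 up, 3 down, median 1.95), heat shock (10 of 13 up, 3 down, median 1.12) and NF-kB genes (14 of 28 up, 8 down, median 0.24) were higher, with adjusted p = 2.02e-09, 3.01e-04, 5.25e-04 and 0.0135. Here the test gave adjusted p = 0.246, 0.163, 0.205 and 0.246 with an estimated correlation. Naive T cell genes were lower (4 up, 21 down of 25, median -2.09, adjusted p = 0.00131, and adjusted p = 0.246 with an estimated correlation). Tpi1 of glycolysis rose from 77.4 ± 8.99 to 1656 ± 119 TPM, Asns of the amino acid response from 9.79 ± 0.905 to 232 ± 5.43 TPM and Srm of the MYC targets from 44.7 ± 2.40 to 248 ± 8.18 TPM. Chek1 of the cell cycle rose from 3.88 ± 0.415 to 39.9 ± 0.907 TPM, Cyp51 of sterol biosynthesis from 41.9 ± 2.95 to 180 ± 4.57 TPM and Hspd1 of heat shock from 184 ± 4.09 to 1029 ± 12.2 TPM.

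Markers of other cells fell with stimulation: 18 of 18 B cell genes (median -2.60), 20 of 20 macrophage genes (-2.43), 14 of 14 neutrophil genes (-2.72) and 6 of 6 mast cell genes (-1.85). Their adjusted p was 2.27e-07, 5.68e-07, 2.75e-05 and 0.0364, and adjusted p = 0.154, 0.154, 0.127 and 0.205 with an estimated correlation. The other lists were not called: T cell receptor machinery (7 up, 19 down of 34, median -0.24, adjusted p = 0.407), Th1 (9 up, 9 down of 19, 0.19, 0.317), Th17 (6 up, 8 down of 18, -0.28, 0.348) and Treg (9 up, 9 down of 19, -0.16, 0.183). Nor were Tfh (5 up, 7 down of 13, -0.32, 0.759), inhibitory receptors (11 up, 11 down of 25, 0.21, 0.185), death receptor genes (14 up, 15 down of 37, 0.01, 0.248) and interferon response (11 up, 12 down of 34, 0.04, 0.157). Migration (5 up, 15 down of 23, -0.71, 0.154), p53 targets (12 up, 9 down of 23, 0.19, 0.223), plasma cells (1 up, 6 down of 9, -1.01, 0.317), dendritic cells (3 up, 6 down of 10, -0.65, 0.618), CD8 T and NK cells (6 up, 6 down of 15, -0.18, 0.282) and erythroid cells (1 up, 8 down of 9, -1.70, 0.0799) were not called either. The mean of the Th17, Treg, Tfh, CD8 and p53 lists had the opposite sign to the median. Adjusted over the list alone, 1 oxidative phosphorylation gene fell, 12 inhibitory receptor genes rose, and all other counts stayed.

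By limma, 10741 of 14035 genes passed, 3857 up and 6884 down, and 5100 of them (1523 up, 3577 down) also changed by a log2 fold change of 1 or more. The median gene changed by -0.32, and with median-of-ratios scaling 10646 genes passed, 5362 up and 5284 down (50.4% up against 35.9% unscaled). Changes are therefore relative to the total of each library. Under scaling Lck moved from -0.23 to 0.11, Cflar from -0.07 to 0.26 and the median of the receptor machinery list from -0.24 to 0.09. The medium and stimulated libraries did not overlap in 84.5% of genes, where 20% would be so by chance.

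**Figure D1:**
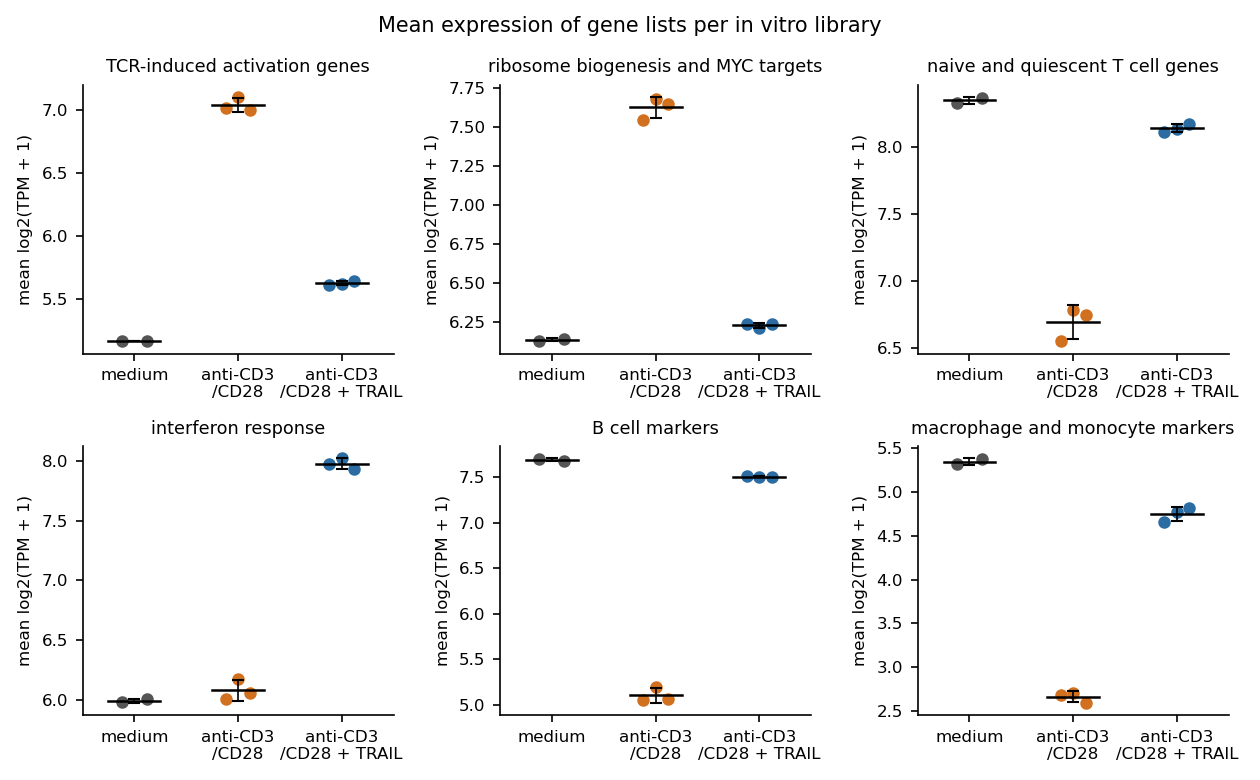
Mean log2(TPM + 1) of 6 gene lists in each culture library, for cells in medium (n = 2), with antibodies to CD3 and CD28 (n = 3) and with the antibodies and TRAIL (n = 3). The line is the group mean and the bar its SD.

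The second culture comparison asked what TRAIL changed in cells stimulated through CD3 and CD28. With TRAIL (n = 3), activation genes were lower as a list than with the antibodies alone (n = 3), with adjusted p = 0.0452 with an estimated correlation. Naive T cell and interferon response genes were higher as lists with the preset correlation only, with adjusted p = 0.267 and adjusted p = 0.133 with an estimated correlation. Il21 fell from 433 ± 9.19 to 0.898 ± 0.0901 TPM (log2 fold change -7.84 ± 0.077 SE, adjusted p = 1.85e-09) and Gzmb from 1567 ± 48.2 to 61.9 ± 5.99 TPM (-4.64, adjusted p = 1.84e-08). Il2ra fell from 906 ± 123 to 124 ± 5.77 TPM (-2.86) and Irf4 from 690 ± 119 to 56.1 ± 0.692 TPM (-3.58). Ifng fell far less, from 78.4 ± 18.2 to 47.8 ± 8.82 TPM (-0.70, adjusted p = 0.00770), and Tnf stayed (36.8 ± 6.44 against 41.0 ± 1.46 TPM, adjusted p = 0.235). Il7r rose from 42.9 ± 5.69 to 443 ± 17.8 TPM, S1pr1 from 30.2 ± 5.81 to 337 ± 11.4 TPM and Bcl6 from 5.65 ± 1.01 to 58.8 ± 2.29 TPM (3.35, 3.45 and 3.18). Ifit3, an interferon-induced gene, rose from 16.2 ± 2.17 to 534 ± 15.0 TPM (4.96, adjusted p = 2.33e-08), and Oasl2 from 25.1 ± 5.80 to 524 ± 23.2 TPM (4.35).

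Ifit1bl1, Slc28a2b, Marco, Ifi213, Ifit3, Rapgef4, Fcmr, Art2b, Ifit3b and BC106179 had the 10 largest rises with TRAIL. Il21, Crabp2, Cth, Egln3, Gzmb, Ak4, Akr1c18, Lif, Il13 and Tg had the 10 largest falls. Myc fell from 619 ± 40.3 to 133 ± 9.18 TPM (-2.22), Lag3 to 27.8 ± 2.54 TPM (-3.86) and Tbx21 to 22.8 ± 0.694 TPM (-2.34). Cd69 fell to 126 ± 12.9 TPM (-1.92) and Casp6 from 219 ± 30.5 to 23.9 ± 1.54 TPM (-3.14). Il2 fell by -3.20, Il17a by -1.55, Gata3 by -1.47 and Csf2 by -1.20 in log2 fold change. Foxp3, Cd4 and Casp8 rose by 1.34, 0.87 and 0.61. Tnfrsf10b fell from 9.10 ± 1.29 to 4.79 ± 0.122 TPM (-0.79, adjusted p = 2.19e-04). Tnfsf10 rose from 8.77 ± 0.612 to 32.4 ± 1.39 TPM (1.77). Lck (0.08, adjusted p = 0.148; -0.19 scaled), Cflar, Il17f and Mki67 (0.13, adjusted p = 0.730) did not pass.

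Of 40 activation genes 3 rose and 33 fell with TRAIL, with a median log2 fold change of -1.50 (adjusted p = 5.47e-12, and adjusted p = 0.0452 with an estimated correlation). Ribosome biogenesis and MYC targets (0 up, 29 down of 30, median -1.47) and ER stress and amino acid response genes (2 up, 26 down of 29, median -0.90) fell under both settings. Each had adjusted p = 0.0154 with an estimated correlation. Glycolysis (2 up, 17 down of 20, median -2.12), cell cycle (0 up, 37 down of 46, -1.11), sterol biosynthesis (0 up, 20 down of 22, -1.07) and oxidative phosphorylation genes (1 up, 29 down of 33, -0.69) were lower with adjusted p = 5.80e-09, 3.12e-13, 5.09e-09 and 5.80e-09. For these the test gave adjusted p = 0.106, 0.133, 0.106 and 0.283 with an estimated correlation. Th2 (4 up, 8 down of 13, -1.47) and heat shock genes (3 up, 9 down of 13, -0.73) were lower with adjusted p = 0.00385 and 0.00172. Each had adjusted p = 0.243 with an estimated correlation. Interferon response genes rose in 33 of 34 cases (0 down, median 2.02, adjusted p = 5.80e-09, and adjusted p = 0.133 with an estimated correlation). Naive T cell genes rose in 20 of 25 (4 down, median 1.57, adjusted p = 0.00135, and adjusted p = 0.267 with an estimated correlation).

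Markers of other cells were higher with TRAIL than with the antibodies alone: 18 of 18 B cell genes (median 2.38), 20 of 20 macrophage genes (1.91), 14 of 14 neutrophil genes (2.16) and 6 of 6 mast cell genes (1.37). Adjusted p was 1.07e-07, 6.94e-07, 2.05e-04 and 0.0199, and adjusted p = 0.144, 0.144, 0.144 and 0.174 with an estimated correlation. Lyz2 rose from 6.38 ± 1.27 to 157 ± 19.0 TPM and Cd79a from 20.8 ± 0.850 to 227 ± 1.80 TPM. Lists not called were T cell receptor machinery (17 up, 8 down of 34, median 0.24, or -0.03 scaled, adjusted p = 0.703), Th1 (10 up, 7 down of 19, 0.76, 0.829), Th17 (9 up, 7 down of 18, 0.19, 0.567) and Treg (9 up, 9 down of 19, 0.19, 0.263). The same held for Tfh (7 up, 5 down of 13, 0.62, 0.866), inhibitory receptors (12 up, 8 down of 25, -0.02, 0.664) and death receptor genes (16 up, 13 down of 37, 0.13, 0.567). NF-kB targets (13 up, 10 down of 28, 0.08, 0.664), migration (15 up, 5 down of 23, 0.67, 0.107) and p53 targets (9 up, 11 down of 23, -0.12, 0.370) were not called. Among other cells, plasma cells (7 up, 1 down of 9, 0.88, 0.196), dendritic cells (7 up, 2 down of 10, 0.55, 0.300), CD8 T and NK cells (4 up, 4 down of 15, 0.003, 0.335) and erythroid cells (8 up, 0 down of 9, 0.85, 0.113) were not called. The median and mean of the Th17, Treg, NF-kB, CD8 and inhibitory lists differed in sign, and the Tfh and death receptor lists had a positive median and mean with a test direction down. Adjusted over the list alone, 1 more oxidative phosphorylation gene and 1 more death receptor gene fell, 1 more naive gene and 1 more p53 target rose, and 1 CD8 gene fewer rose.

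By limma, 10765 of 14035 genes passed, 6746 up and 4019 down. Of these, 4279 had a log2 fold change of at least 1 either way (3049 up, 1230 down). The median gene changed by 0.25, and 10777 genes passed with scaling (50.1% up against 62.7%). The libraries of these groups did not overlap in 80.5% of genes, where 10% would be so by chance.

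**Figure D2:**
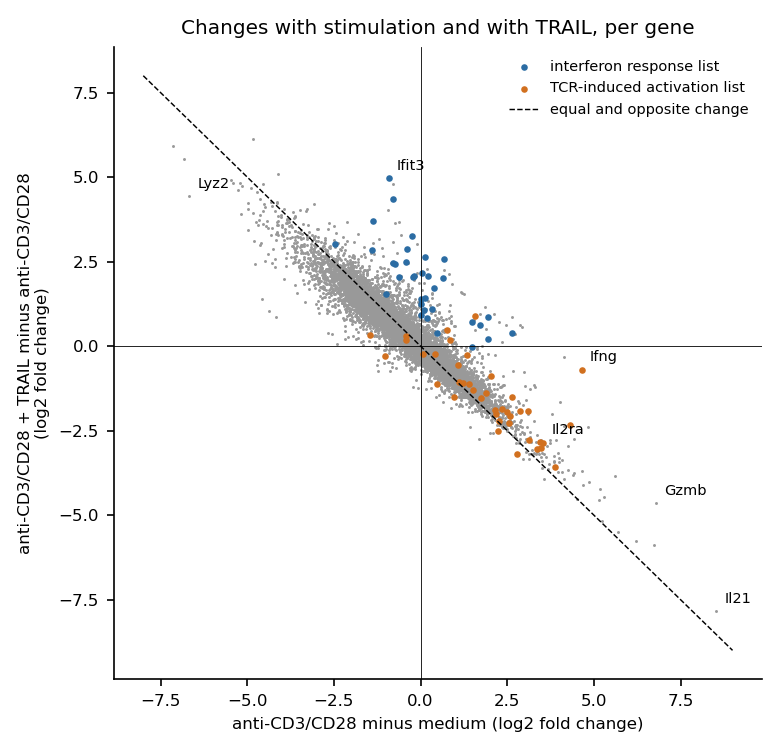
Log2 fold change of each gene with stimulation (anti-CD3/CD28 minus medium) and with TRAIL (anti-CD3/CD28 + TRAIL minus anti-CD3/CD28), with the interferon list in blue and the activation list in orange. The dashed line marks an equal and opposite change.

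Gene by gene, the changes with stimulation and with TRAIL were opposite. Of the genes raised by the antibodies 3500 fell with TRAIL and 85 rose. Of the genes lowered by them 6240 rose and 16 fell. This reversed 90.7% of the raised and 90.6% of the lowered genes, across 14035 genes that are not independent. Markers of B cells, macrophages and neutrophils also fell and rose again, and a changed share of these cells was not separated from changes within T cells. The correlation was -0.938, where simulations without a group effect gave a mean of -0.449 (-0.483 to -0.414) because both changes use the same stimulated libraries. The covariance was -1.15 against -0.0116 simulated, a difference of -1.14. The simulations carry only the spread between libraries. A state particular to the stimulated libraries would enter both changes with opposite sign, so the size of this excess does not measure a reversal by TRAIL. How near the TRAIL libraries lie to medium is shown by the third culture comparison.

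The third culture comparison asked which genes differed between cells stimulated with TRAIL (n = 3) and cells in medium (n = 2). Among the genes with the largest differences were interferon-induced genes, the Th1 cytokine gene Ifng and some myeloid or platelet genes. The macrophage list and the erythroid and platelet list were called lower with the preset correlation only. Ifng rose from 2.13 ± 0.180 to 47.8 ± 8.82 TPM (log2 fold change 3.95, adjusted p = 1.33e-05) and Ifit3 from 31.5 ± 2.62 to 534 ± 15.0 TPM (4.04, adjusted p = 9.42e-07). Cxcl10 rose from 5.36 ± 0.495 to 70.3 ± 2.23 TPM (3.49, adjusted p = 9.42e-07) and Isg15 from 12.1 ± 0.105 to 104 ± 5.66 TPM (3.0). Nos2, the inducible nitric oxide synthase gene, rose from 0.192 ± 0.00132 to 15.8 ± 1.49 TPM (3.82, adjusted p = 9.44e-06). Cd274, which encodes the checkpoint ligand PD-L1, rose from 96.1 ± 0.114 to 286 ± 10.5 TPM (1.56) and Socs1 from 27.2 ± 1.93 to 90.4 ± 0.811 TPM (1.70). Gzmb stayed above medium (13.3 ± 1.11 to 61.9 ± 5.99 TPM, 2.14, adjusted p = 6.01e-06), as did Tbx21 (5.11 ± 0.199 to 22.8 ± 0.694 TPM, 1.96). Myc (133 ± 9.18 against 128 ± 15.7 TPM, adjusted p = 0.779) and Tnfrsf10b (4.79 ± 0.122 against 4.97 ± 0.238 TPM, adjusted p = 0.860) did not differ. Ppbp of platelets fell from 22.1 ± 1.63 to 1.32 ± 0.381 TPM (-3.33) and Lyz2 from 747 ± 38.3 to 157 ± 19.0 TPM (-2.25, adjusted p = 6.06e-05).

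Ifit3, Ifit3b, Ifng, Nos2, Oasl2, Serpina3f, Cxcl10, Ptgs2, Ifi44 and Cxcl9 rose most. Ppbp, Igf1, Pf4, Slc40a1, F13a1, Mrc1, Lyz2, Retnlg, Chil5 and Fabp4 fell most. Il21 was 0.898 ± 0.0901 TPM with TRAIL (0.69, adjusted p = 0.00138) and Il2ra 124 ± 5.77 TPM (0.68, adjusted p = 0.00542). Il7r was 443 ± 17.8 TPM (-0.80, adjusted p = 0.00239) and Tnfsf10 32.4 ± 1.39 TPM (0.64, adjusted p = 0.00176). Tnf rose by 1.00, Csf2 by 2.11 and Cd69 by 1.18. Mki67 (0.52, adjusted p = 0.390), Il2 (-0.43, adjusted p = 0.437) and Il17a (0.37, adjusted p = 0.429) did not pass. Neither did Lck (-0.15), Cd4 (-0.21), Foxp3 (0.11), Gata3 (0.16), Casp8 (0.15), Cflar (0.06) and Il17f (0.15), with adjusted p from 0.110 (Lck) to 0.832 (Cflar).

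All 34 interferon response genes rose (median 1.98, adjusted p = 7.15e-50, and adjusted p = 0.0186 with an estimated correlation). Th1 genes (10 up, 0 down of 19, median 0.54, adjusted p = 5.46e-10) and ER stress genes (14 up, 2 down of 29, 0.29, adjusted p = 4.03e-07) were also higher. They had adjusted p = 0.0386 and adjusted p = 0.0255 with an estimated correlation. Activation genes (18 up, 5 down of 40, 0.31), cell cycle (28 up, 0 down of 46, 0.51), NF-kB targets (12 up, 0 down of 28, 0.32) and death receptor genes (10 up, 2 down of 37, 0.04) had adjusted p = 9.68e-10, 1.05e-19, 6.81e-08 and 0.0132. With the other setting they had adjusted p = 0.0549, 0.0686, 0.0674 and 0.0916 with an estimated correlation. Ribosome biogenesis (5 up, 1 down of 30, 0.086), glycolysis (9 up, 1 down of 20, 0.20), oxidative phosphorylation (5 up, 0 down of 33, 0.10) and sterol genes (2 up, 0 down of 22, 0.090) had adjusted p = 0.00204, 6.66e-05, 8.40e-04 and 0.0140. They gave adjusted p = 0.123, 0.144, 0.449 and 0.327 with an estimated correlation. Th2 (7 up, 1 down of 13, 0.53), Th17 (3 up, 1 down of 18, 0.14), Treg (7 up, 3 down of 19, 0.15), inhibitory receptor (8 up, 5 down of 25, 0.18) and heat shock genes (7 up, 0 down of 13, 0.39) had adjusted p = 6.81e-05, 0.0329, 0.0120, 0.0166 and 6.66e-05. For them the test gave adjusted p = 0.123, 0.428, 0.220, 0.442 and 0.144 with an estimated correlation. Naive T cell genes were lower (2 up, 6 down of 25, -0.27, adjusted p = 0.0256, and adjusted p = 0.425 with an estimated correlation).

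Among markers of other cells, macrophage (2 up, 13 down of 20, median -0.77), neutrophil (0 up, 9 down of 14, -0.72) and erythroid genes (1 up, 2 down of 9, -0.59) were lower with TRAIL than in medium. Adjusted p was 4.62e-04, 6.40e-07 and 0.0214, and adjusted p = 0.232, 0.0686 and 0.168 with an estimated correlation. B cell (0 up, 4 down of 18, -0.16, adjusted p = 0.0816), plasma cell (2 up, 0 down of 9, 0.07, 0.139), dendritic (2 up, 1 down of 10, -0.05, 0.448), CD8 T and NK (6 up, 2 down of 15, -0.003, 0.139) and mast cell lists (1 up, 1 down of 6, -0.06, 0.957) were not called. The dendritic and CD8 lists had a positive mean. Nor were T cell receptor machinery (0 up, 7 down of 34, -0.12, adjusted p = 0.0677), Tfh (3 up, 2 down of 13, 0.06, 0.139), migration (4 up, 5 down of 23, -0.05, 0.870) and p53 targets (3 up, 4 down of 23, -0.07, 0.766). Adjusted over the list alone, 23 activation genes and 36 cell cycle genes rose and 11 naive genes fell. So did 6 B cell, 5 CD8 and NK, 6 erythroid, 7 migration, 7 inhibitory receptor, 3 death receptor, 2 glycolysis and 1 heat shock genes. Rises passed for 6 ribosome biogenesis, 11 glycolysis, 4 oxidative phosphorylation, 11 Th1, 4 Th17, 14 NF-kB, 17 ER stress, 10 inhibitory receptor, 5 migration, 3 plasma cell, 3 macrophage and 1 B cell genes, and the other counts stayed.

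By limma, 2411 of 14035 genes passed, 1017 up and 1394 down, and 408 had a log2 fold change of at least 1 either way (234 up, 174 down). This count depended on the fit: 902 genes passed without medium replicate 1, 1356 with a replicate block and 5141 with only the compared groups. The median gene changed by -0.06, and 2396 genes passed with scaling (53.3% up against 42.2%). No overlap was seen in 60.5% of genes, where 20% would show none by chance.

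**Figure D3:**
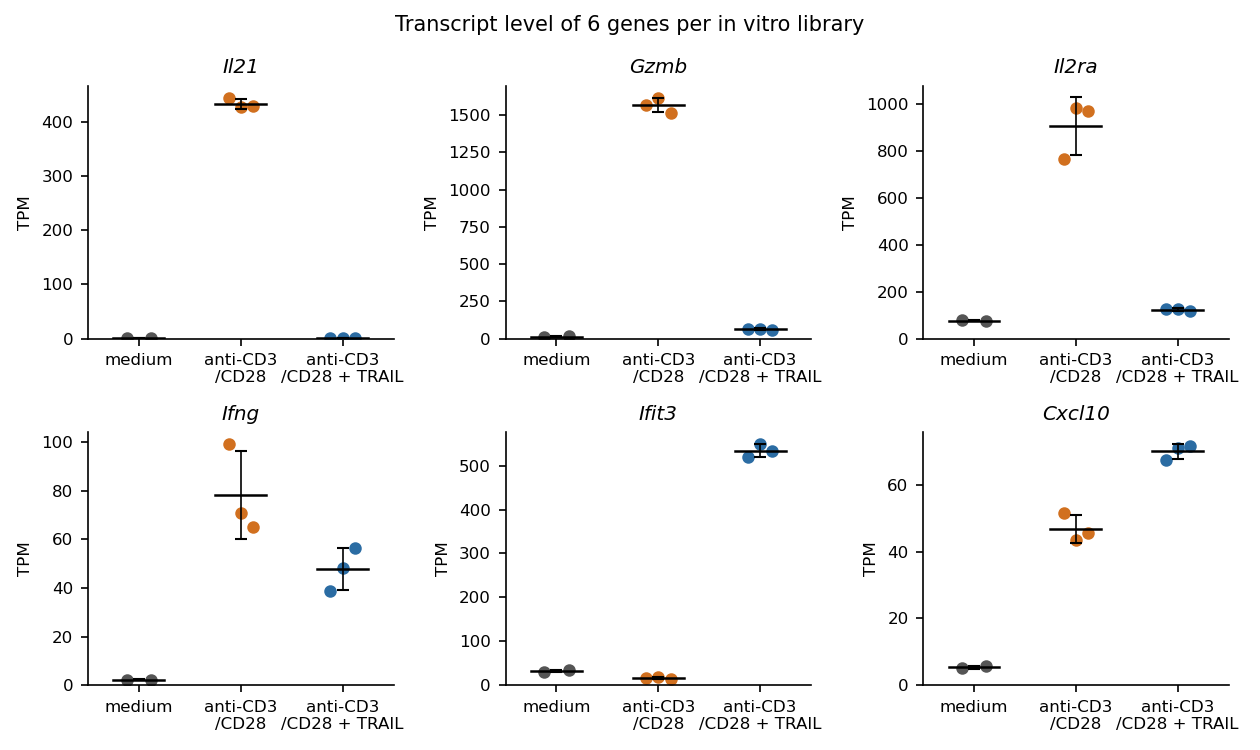
TPM of Il21, Gzmb, Il2ra, Ifng, Ifit3 and Cxcl10 in each culture library (medium n = 2, antibodies n = 3, antibodies with TRAIL n = 3). The line is the group mean and the bar its SD.

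On GRCm38 the genes that mattered most in culture lie at chromosome 3, 37222759 to 37232636 (Il21, ENSMUSG00000027718), chromosome 14, 56258838 to 56262260 (Gzmb, ENSMUSG00000015437) and chromosome 2, 11642807 to 11693193 (Il2ra, ENSMUSG00000026770). Others lie at chromosome 10, 118441046 to 118445892 (Ifng, ENSMUSG00000055170), chromosome 19, 34583531 to 34588731 (Ifit3, ENSMUSG00000074896) and chromosome 15, 61985391 to 61990374 (Myc, ENSMUSG00000022346). Tnfrsf10b (ENSMUSG00000022074) lies on chromosome 14, 69767472 to 69784411, and Tnfsf10 (ENSMUSG00000039304) on chromosome 3, 27317028 to 27342427.

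The mouse libraries are labelled as CD4 T cells. Neutrophil genes averaged 8.81 to 10.56 in log2(TPM + 1) against 5.37 to 6.71 for T cell receptor machinery genes. Changes in these libraries therefore cannot be assigned to CD4 T cells. The bracketed name of Lck-Cre replicate 1, which is on lane 2, carries no TRAIL tag while its title does, and the title was followed. The mouse experiment asked first whether the targeted receptor gene was lower in the libraries labelled Lck-Cre. Tnfrsf10b was 2.04 and 3.50 TPM there (n = 2, 2.77 ± 1.03), 1.64, 1.46 and 2.31 TPM in floxed mice given TRAIL (n = 3, 1.80 ± 0.444) and 1.82 TPM in the vehicle library (n = 1). It was not lower with Lck-Cre (log2 fold change 0.41 ± 0.29 SE, limma adjusted p = 0.9998), also with lane in the fit (0.46) and within lane 2 (0.20) and lane 4 (0.66). Whole-gene TPM cannot show the loss of a single floxed exon, since reads outside it may remain, and cells other than T cells in a library can express the gene.

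The next comparison asked what differed in the libraries of floxed mice given TRAIL (n = 3) against the vehicle library (n = 1). No single gene passed. With the preset correlation, cell cycle, heat shock and interferon genes were higher as lists and T cell receptor genes lower with TRAIL, and none of these calls held, with adjusted p = 0.873 at the lowest with an estimated correlation. The interferon median of 0.81 was 0.14 with lane in the fit. The mean of the cell cycle list was 6.59, 6.47 and 6.53 with TRAIL and 5.86 with vehicle, and that of the interferon list 5.29, 6.72 and 5.39 against 4.94. The receptor machinery list stood at 5.37, 6.35 and 6.51 against 6.60. Mki67 was 359 ± 103 TPM with TRAIL and 258 TPM with vehicle, Lck 121 ± 51.4 and 209 TPM, Cd4 133 ± 70.4 and 204 TPM and Ifng 4.06 ± 2.93 and 1.16 TPM. Myc (137 ± 54.5 and 106 TPM), Tbx21 (11.6 ± 6.31 and 5.80), Il2ra (12.4 ± 5.38 and 14.1), Foxp3 (15.5 ± 8.24 and 16.7), Casp8 (78.3 ± 1.33 and 92.0), Cflar (114 ± 11.4 and 116) and Tnfsf10 (15.3 ± 6.55 and 14.1) did not pass either. The same held for Cd69 (133 ± 75.9 and 108), Tnf (19.3 ± 3.99 and 21.4) and Gata3 (22.4 ± 12.3 and 25.5), and Il17a, Il17f and Csf2 lay below the filter. On lane 2 alone, where the vehicle library and 1 floxed TRAIL library lie, the log2 fold changes were -1.19 for Cd69, -0.69 for Tnfsf10, -0.45 for Myc and -0.25 for Tbx21, opposite to the means above, and 0.15 for Ifng. There Cd4 changed by -1.84, Lck by -1.73, Gata3 by -1.43, Foxp3 by -1.30, Il2ra by -1.06 and Mki67 by 0.89. Genes with the smallest p-values were antibody segments of B cells, given as values. Ighv1-34 (ENSMUSG00000093955, chromosome 12, 114851190 to 114851660) was at 51.8 ± 9.33 against 4.20 TPM and Igkv5-48 at 358 ± 62.0 against 57.0. Ighv13-2 was at 567 ± 222 against 14.3, Ighv1-64 at 1430 ± 81.9 against 318 and Igkv4-74 at 83.5 ± 16.4 against 9.32.

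Higher with TRAIL were cell cycle (45 of 46 members higher, median 0.65, adjusted p = 4.39e-15), heat shock (16 of 16, 0.97, 4.68e-06), ER stress (0.62, 2.17e-06), interferon response (31 of 34, 0.81, 9.15e-05), sterol (0.47, 1.49e-05), ribosome biogenesis (0.43, 1.81e-04), glycolysis (0.46, 0.00963), activation (0.45, 0.0131) and macrophage genes (0.23, 0.0131). Lower were receptor machinery (27 of 34 lower, -0.66, 4.81e-05), naive (-0.49, 7.93e-06), erythroid (-0.77, 4.68e-06) and CD8 and NK genes (-0.29, 0.0421). None held when the correlation was estimated, with adjusted p = 0.873 to adjusted p = 0.916 with an estimated correlation. Over all genes no list member passed, and adjusted over the list alone 5 erythroid genes fell and no other did. Markers of other cells were not called for B cells (median -0.10), plasma cells (0.42), neutrophils (-0.33), dendritic cells (0.31), stromal cells (-0.27) and mast cells (0.06). Oxidative phosphorylation (0.17), Th1 (0.08), Th17 (0.18), Th2 (0.32), Treg (-0.23), Tfh (-0.02), inhibitory receptors (0.14), death receptor genes (0.05), NF-kB (0.29), migration (0.03) and p53 targets (0.07) were not called either, with adjusted p from 0.144 to 0.963. With lane in the fit the medians were -1.43 for receptor machinery, 0.053 for ribosome biogenesis and -0.12 for activation genes, and the interferon, ribosome biogenesis and activation calls were lost. Lane 2 holds the vehicle library and 1 floxed TRAIL library. The medians there were 0.47 for heat shock, 0.30 for sterol, 0.59 for ER stress and 0.75 for cell cycle genes. They were 0.66 for macrophage, -0.99 for naive, -0.83 for CD8 and NK and -1.20 for erythroid genes. Of the other marker lists, neutrophils were at 0.49, mast cells 0.66, plasma cells 0.012, dendritic cells 0.013, B cells -0.78 and stromal cells -0.78. The neutrophil median on lane 2 was opposite in sign to the one over all libraries, and receptor machinery stood at -1.60. Without floxed TRAIL replicate 1 the CD8 and NK (median -0.020, adjusted p = 0.277), glycolysis (0.27, 0.186) and macrophage calls (0.31, 0.394) were lost, and without replicate 2 the activation call (0.40, 0.121). By limma 0 of 14176 genes passed, 566 had an unadjusted value under 0.05 (959 by voom, with 0 calls), and the smallest adjusted p was 0.3535. A gene changed 4-fold would not have been found at this size. No overlap was seen in 50.8% of genes, where 50% would show none by chance.

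The comparison of Lck-Cre (n = 2) with floxed libraries (n = 3), all titled as given TRAIL, asked what differed with the Lck-Cre label. Deletion of the receptor in T cells is implied by that label only, since Tnfrsf10b was not lower. No single gene passed. With the preset correlation, libraries labelled Lck-Cre had higher T cell receptor machinery genes and lower interferon and cell cycle genes, and none of these calls held, with adjusted p = 0.994 with an estimated correlation. Lck was 176 ± 41.8 TPM with Lck-Cre and 121 ± 51.4 TPM without, Cd4 180 ± 60.7 and 133 ± 70.4 TPM, Mki67 267 ± 52.3 and 359 ± 103 TPM and Ifng 3.09 ± 2.19 and 4.06 ± 2.93 TPM. With Lck-Cre, Myc was 124 ± 42.4 TPM, Tbx21 10.5 ± 6.05, Il2ra 12.7 ± 6.25, Foxp3 17.8 ± 10.3, Casp8 77.3 ± 2.32, Cflar 117 ± 11.8, Tnfsf10 14.8 ± 5.46, Cd69 136 ± 66.7, Tnf 18.3 ± 0.175 and Gata3 26.2 ± 17.1 TPM. The mean of the interferon list was 4.28 and 5.44 with Lck-Cre against 5.29, 6.72 and 5.39, and that of the cell cycle list 5.95 and 6.32 against 6.59, 6.47 and 6.53. For the receptor machinery list it was 6.19 and 6.71 against 5.37, 6.35 and 6.51. The genes with the smallest p-values (adjusted p = 0.9998 for each) were Rn7sk, Gm22513 and 3 genes that overlap ribosomal RNA sequences, Mir6236, Gm23935 and CT010467.1, all higher in both Lck-Cre libraries than in every floxed library with TRAIL. Rn7sk (ENSMUSG00000065037, chromosome 9, 78175303 to 78175633) was at 41.8 ± 9.25 against 8.04 ± 2.21 TPM and Mir6236 at 2562 ± 326 against 872 ± 21.4. Gm22513 was at 7.78 ± 0.377 against 0.969 ± 0.659, Gm23935 at 5534 ± 1252 against 1773 ± 402 and CT010467.1 at 2965 ± 690 against 1077 ± 270.

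Lower with Lck-Cre were interferon response (34 of 34 members lower, median -0.82, adjusted p = 5.52e-17), cell cycle (45 of 46, -0.40, 5.52e-17), heat shock (-0.45, 1.36e-04), ER stress (-0.21, 0.00209), sterol (-0.21, 0.00209), ribosome biogenesis (-0.19, 0.00841), glycolysis (-0.16, 0.0416) and dendritic cell genes (-0.52, 0.0416). Higher were receptor machinery (26 of 34 higher, 0.50, 4.23e-06), naive (0.24, 4.27e-05) and erythroid genes (0.26, 0.0416). All were lost when the correlation was estimated, with adjusted p = 0.994 with an estimated correlation. Several also depended on single libraries. The leave-one-out fits had no lane term, and leaving out a library changes the balance of lanes, so they mix lane with library. Leave-one-out medians spanned -1.33 to -0.30 for interferon and -0.54 to -0.19 for cell cycle genes, each smallest without Lck-Cre replicate 1. The erythroid list had a median of 0.26 and a mean of -0.051. The receptor machinery median was 0.0033 (adjusted p = 0.0852) without floxed TRAIL replicate 1, and leave-one-out medians spanned -0.56 to 0.19 for ribosome biogenesis and -1.07 to 0.12 for dendritic cell genes. Without Lck-Cre replicate 1 the heat shock median was 0.15 and the sterol median 0.044, without Lck-Cre replicate 2 the naive median was -0.037, and without floxed TRAIL replicate 2 the ER stress median was -0.049, each with its call lost. Glycolysis and erythroid lists changed test direction without Lck-Cre replicate 2, and the dendritic and erythroid calls were lost with lane in the fit. Within lane 2 and lane 4 the medians were 1.04 and 0.37 for receptor machinery, -0.66 and -0.15 for cell cycle and -0.91 and -0.56 for interferon genes. Heat shock (-0.39 and -0.18), naive (0.53 and 0.26), glycolysis (-0.22 and -0.21), sterol (-0.25 and -0.021) and ER stress genes (-0.0080 and -0.32) also kept their sign. Ribosome biogenesis (-0.19 and 0.00059), dendritic (-0.61 and 0.056) and erythroid genes (-0.046 and 0.52) did not. Markers of other cells not called were those of B cells (-0.04), plasma cells (-0.03), macrophages (-0.07), neutrophils (-0.10), CD8 T and NK cells (0.17), stromal cells (0.09) and mast cells (-0.20). Activation (-0.15), oxidative phosphorylation (-0.05), Th1 (0.07), Th17 (-0.01), Th2 (-0.09), Treg (0.13), Tfh (0.14), inhibitory receptors (0.03), death receptor genes (-0.03), NF-kB (-0.12), migration (-0.04) and p53 targets (-0.09) were not called, with adjusted p from 0.0912 to 0.988, and the mean of the Th1, Th17 and migration lists had the opposite sign to the median. By limma 0 of 14176 genes passed and 106 had an unadjusted value under 0.05 (160 by voom, with 0 calls). Simulated 4-fold changes were found in 34.8% of genes, and 11.3% of genes showed no overlap where 20% would by chance.

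**Figure D4:**
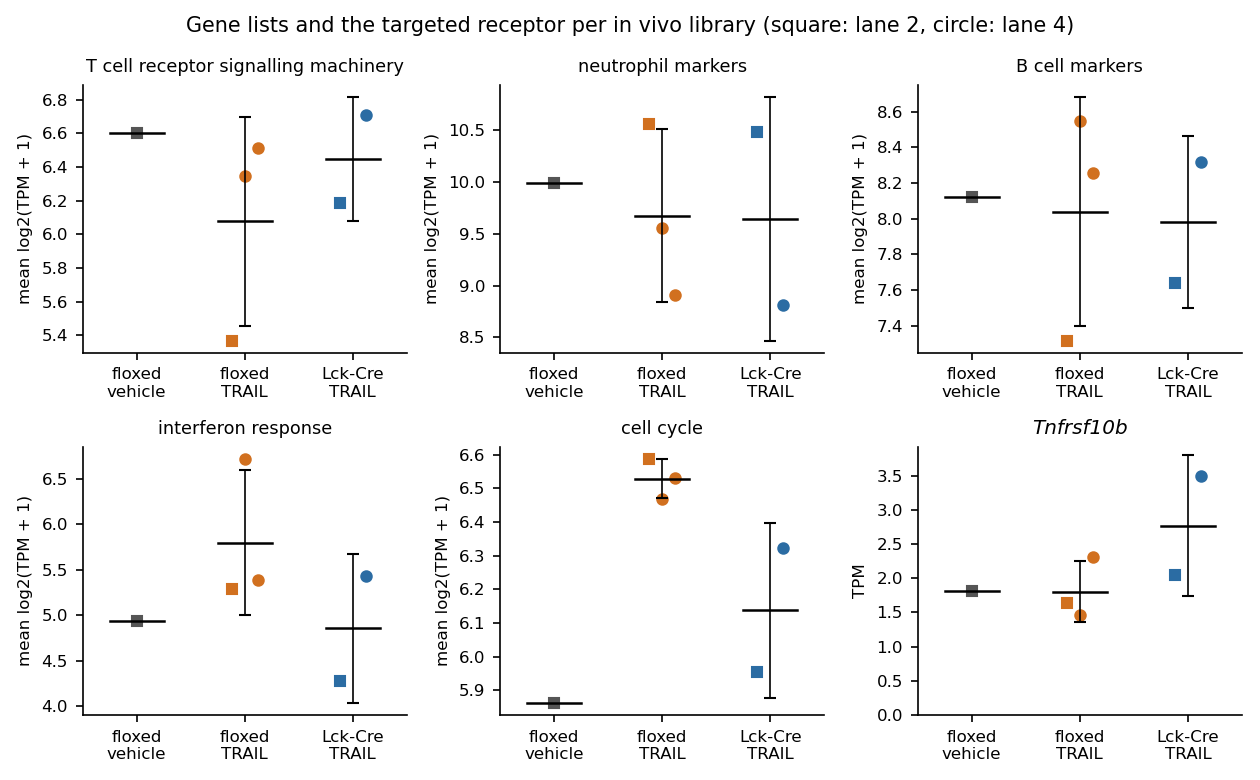
Mean log2(TPM + 1) of 5 gene lists and TPM of Tnfrsf10b in each mouse library (vehicle n = 1, floxed with TRAIL n = 3, Lck-Cre with TRAIL n = 2). Squares are lane 2 libraries, circles lane 4 libraries, the line the group mean and the bar its SD.

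The last comparison asked how Lck-Cre libraries with TRAIL (n = 2) differed from the vehicle library (n = 1). Cell cycle genes were higher (median 0.31, adjusted p = 4.43e-07), as were ER stress (0.37, 2.57e-06), heat shock (0.50, 1.32e-04), macrophage (0.63, 1.23e-04), sterol (0.27, 1.61e-04), ribosome biogenesis (0.26, 0.00292), activation (0.28, 0.0160), plasma cell (0.59, 0.0221) and glycolysis genes (0.28, 0.0454). Erythroid (-0.79, 5.05e-09) and naive genes (-0.20, 6.24e-04) were lower. None held when the correlation was estimated, with adjusted p = 0.833 to adjusted p = 0.959 with an estimated correlation. Receptor machinery (-0.12), interferon (0.07), B cell (-0.14), neutrophil (-0.34) and the other lists were not called, with adjusted p from 0.0732 to 0.911, and the mean of the interferon and Tfh lists had the opposite sign to the median. The only vehicle library is on lane 2, and with lane in the fit the medians were -0.12 for activation, -0.071 for ribosome biogenesis and 0.15 for heat shock genes, none of them called. Interferon (-0.44) and receptor machinery (-0.68) were then called lower with the preset correlation, among 16 lists, 8 up and 8 down. Within lane 2 the medians were -0.13 for ribosome biogenesis, -0.60 for interferon and -0.45 for receptor machinery genes. They were 0.12 for cell cycle, -1.63 for erythroid and -0.43 for naive genes there. B cell genes were at -0.48 within lane 2, and neutrophil genes at 0.43, opposite in sign to their median over all libraries. Without Lck-Cre replicate 1 the naive median turned to 0.24 and the ER stress, plasma cell and macrophage calls were lost. Without replicate 2 the heat shock median was 0.063 and the sterol median 0.044, with both calls lost. Ighv1-34 was 39.5 ± 0.904 TPM, Ighv13-2 471 TPM and Igkv5-48 386 TPM with Lck-Cre. By limma 0 of 14176 genes passed, 132 had an unadjusted value under 0.05 (158 by voom, with 0 calls), and the smallest adjusted p was 0.5049. No overlap was seen in 40.8% of genes, where 66.7% would show none by chance.

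The final question was whether genes changed by TRAIL in culture moved in the mice. Genes raised by TRAIL in culture (6317 measured) had a median change of 0.0045 with Lck-Cre against floxed libraries (adjusted p = 9.10e-04) and of -0.02 with TRAIL against vehicle (adjusted p = 1.27e-04). Genes lowered in culture (3794 measured) had medians of -0.11 (adjusted p = 2.89e-05) and 0.23 (adjusted p = 2.77e-06). The median of all genes was -0.04 and 0.07. Relative to all genes, both sets thus moved opposite to culture with TRAIL against vehicle. With Lck-Cre against floxed libraries they moved the same way as with TRAIL in culture. The sets together make up most of the 14176 tested genes, so each was compared largely with the other. Neither set held when the correlation was estimated, with adjusted p = 0.440 and adjusted p = 0.380 with an estimated correlation. With lane in the fit the medians were 0.043 and -0.072 for Lck-Cre and -0.18 and 0.049 for TRAIL against vehicle. No mouse gene passed, so single genes could not be matched.

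The authors' own culture tests passed 13061 genes for stimulation, 12916 for TRAIL against stimulation and 2597 for TRAIL against medium. Of these 8921, 9168 and 1955 passed both there and here, 99.7%, 99.9% and 100% of them in the same direction. Their calls were 6278 up and 6783 down for stimulation and 6696 up and 6220 down for TRAIL against stimulation. Over the genes compared, their median change was 0.036 and -0.026, against -0.32 and 0.25 in the unscaled fit here. The skew of the unscaled calls was thus not seen in their tests. Their mouse table names no comparison. It passed 0 genes (smallest adjusted p 0.2706), and its fold changes had a correlation of -0.966 with the Lck-Cre minus floxed changes with lane in the fit. With that sign, genes lowered in their table are those higher with Lck-Cre here, as Lck was (-0.76 in their table). The authors' over-representation of lowered genes lists 113 sets, with T cell receptor signalling (22 genes, adjusted p = 4.52e-11) among them, that of raised genes 37 sets, and 1630 of 2439 sets of their enrichment test had q under 0.05. These tables come from the same libraries and are not independent of the results here.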

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

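The single genes followed under the alternatives were the named genes. In culture most of these were picked for large changes past the threshold, which favours stability. Of their values, 1770 of 1781 for stimulation and 1797 of 1820 for TRAIL against stimulation kept their direction and side of the threshold, with 2 reversed in each. For TRAIL against medium 1489 of 1647 did and 148 lost the threshold. Among all genes that passed, median-of-ratios scaling kept the call and direction of 9141 of 10741 for stimulation and 9419 of 10765 for TRAIL against stimulation. In the mice no gene passes by the main fit and the simulations recovered few or none, so staying on that side says nothing about stability. List results stayed in 122 of 135, 123 of 135 and 160 of 180 cases in culture and in 58 of 78 (TRAIL against vehicle), 66 of 99 (Lck-Cre against floxed) and 31 of 55 (Lck-Cre against vehicle) in the mice, where 9 reversed. A higher correlation widens the list test by construction, and for the other changes below the cause was not tested. DESeq2, the edgeR fit and TMM or RLE factors in it were planned for deposited counts and not run. Voom was run in their place on reads recovered from TPM and gene length. That fit (10714, 10788 and 2741 genes in culture), the single-lane fits, scaling of the list tests and the estimated correlation for the culture gene sets were chosen after seeing the data.

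In culture, a minimum absolute log2 fold change of 1 left 5100 genes for stimulation, 4279 for TRAIL against stimulation and 408 for TRAIL against medium. Leave-one-out gave 9290 to 11447 genes for stimulation and 10009 to 11385 for TRAIL against stimulation. For TRAIL against medium it gave 902 (without medium replicate 1) to 1534, and 5141 genes passed when only these groups were fitted. With a replicate block on the title numbers 1356 genes passed there, and 1549 with the bracketed number of a medium library. With an estimated correlation 3 lists were called in each culture comparison and 0 in each mouse comparison. Under median-of-ratios scaling Lck reversed for stimulation (0.11 from -0.23) and for TRAIL against stimulation (-0.19 from 0.08), as did Cflar for stimulation (0.26 from -0.07). Mki67 for TRAIL against stimulation went from 0.13 to -0.32 without stimulated replicate 1 and 0.38 without replicate 2. The correlation of stimulation and TRAIL changes was -0.932 without the filter and -0.940 to -0.934 when each stimulated library was left out, the only libraries left out for it.

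In the mice, 0 genes passed under any setting except Lck-Cre against vehicle with only these groups, where 15 passed on 3 libraries. Tnfrsf10b stayed higher with Lck-Cre in every setting (0.13 to 0.69 in leave-one-out). A lane block reversed the activation list for TRAIL against vehicle (-0.12 from 0.45) and for Lck-Cre against vehicle (-0.12 from 0.28). For Lck-Cre against floxed libraries, leave-one-out spanned -0.56 to 0.19 for ribosome biogenesis, -1.07 to 0.12 for dendritic, -0.26 to -0.019 for glycolysis and 0.064 to 0.50 for erythroid genes, and the list test changed direction at the end nearer to or past 0. For Lck-Cre against vehicle it spanned -0.22 to 0.89 for activation, -0.13 to 0.62 for ribosome biogenesis and 0.015 to 0.32 for glycolysis, with 7 (without Lck-Cre replicate 1) to 13 lists called. The culture gene sets, with medians of 0.0045 and -0.11 (Lck-Cre against floxed) and -0.022 and 0.23 (TRAIL against vehicle), lost their calls with an estimated correlation. Their medians were 0.043, -0.072, -0.18 and 0.049 with a lane block and 0.071, -0.24, -0.20 and 0.52 with 200 genes each way, with the test direction kept. The receptor machinery list for Lck-Cre against floxed libraries lost its call without floxed TRAIL replicate 1 (median 0.0033 from 0.50). Depth left 20.4 to 67.4 reads behind 1 TPM, which limits genes near or below that level.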

Other observations

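Jun and Fos moved apart in cells stimulated with TRAIL (n = 3) against cells in medium (n = 2). Jun rose from 43.9 ± 5.26 to 243 ± 23.3 TPM (log2 fold change 2.45, adjusted p = 8.15e-06), and Fos fell from 22.6 ± 4.07 to 8.43 ± 0.853 TPM (-1.32, adjusted p = 0.00413). Il12rb2, a receptor gene of the Th1 pathway, was 5.54 ± 0.719 TPM in medium, 189 ± 42.8 TPM with the antibodies and 34.7 ± 3.22 TPM with the antibodies and TRAIL. Mlkl, which encodes the effector of necroptosis, rose from 5.57 ± 0.165 to 21.4 ± 2.94 TPM with the antibodies and was 17.3 ± 0.972 TPM with TRAIL. Higher with TRAIL than with the antibodies alone were Ifngr1 at 1099 ± 31.1 against 172 ± 10.0 TPM and Il18r1 at 72.9 ± 0.549 against 9.19 ± 1.27 TPM.

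Slc40a1 and Pf4 fell in both stimulated groups. Slc40a1, the iron exporter gene of macrophages, was 53.6 ± 1.56 TPM in medium, 0.996 ± 0.207 TPM with the antibodies and 9.68 ± 1.22 TPM with TRAIL, and Pf4 of platelets 72.3 ± 2.87, 2.21 ± 1.00 and 7.13 ± 0.648 TPM. Against medium, Igf1 fell with TRAIL from 21.1 ± 0.634 to 1.21 ± 0.0285 TPM and Mrc1 from 8.92 ± 0.135 to 1.03 ± 0.225 TPM. In the same comparison Irf8 rose from 190 ± 7.51 to 406 ± 8.91 TPM, Ptgs2 from 3.60 ± 0.143 to 50.3 ± 2.82 TPM and Cxcl9 from 0.945 ± 0.205 to 15.5 ± 1.60 TPM. Which cells carried these changes was not tested.

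Some values concern single libraries. Stimulated replicate 1 had a correlation of 0.984 and 0.985 with the other stimulated libraries, which had 0.995 with each other. The chi-square per gene, a measure of the difference between libraries, was 72.8 and 61.6 for these pairs with replicate 1. It was 2.76 between stimulated replicates 2 and 3, 4.55 between the medium libraries and 2.50 to 3.30 among those with TRAIL. Apart from stimulated replicate 1, culture replicates were thus close. Culture p-values may therefore not cover the variation between separate cultures, which was not tested. Floxed TRAIL replicate 3 and Lck-Cre TRAIL replicate 2, both on lane 4, had a correlation of 0.993, above the 0.979 of the closest mouse libraries that share a group, and the Lck-Cre libraries had 0.940. A mislabelled or swapped library was not tested and is not excluded, and it would change every value of Lck-Cre against floxed libraries. The 10 most abundant genes held 14.3%, 13.9% and 15.4% of the TPM in the lane 2 mouse libraries and 8.5%, 9.39% and 9.20% in those of lane 4. Neutrophil genes averaged 10.56, 9.99 and 10.48 on lane 2 (floxed TRAIL, vehicle, Lck-Cre) and 9.56, 8.91 and 8.81 on lane 4 (floxed TRAIL, floxed TRAIL, Lck-Cre). Mir6236, which lies in a ribosomal RNA locus, was 892, 875 and 849 TPM in floxed libraries with TRAIL, 975 TPM with vehicle and 2332 and 2792 TPM with Lck-Cre.

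The tests in the paragraphs below were chosen after their results had been seen, apart from those named next. The splits of libraries, the estimated correlation in the list test and the leave-one-out fits were planned before. The first pattern is that genes raised by the antibodies lay near the medium level with TRAIL. The tables argue against scaling as the whole cause, since the activation list fell by -1.68 ± 0.0480 after median-of-ratios scaling and by -1.42 before it. They also argue against a mixture in which TRAIL left 1 fixed share of cells stimulated as the whole cause. Of 312 genes raised 4-fold or more by the antibodies, 64.1% lay more than 2 standard errors from the median position. That median was 5.33% of the way from medium to stimulated (-0.581% to 40.4% for the 5th to 95th percentile, 2.18% to 11.6% for the 25th to 75th). Of these genes 28 lay at or below medium and 9 at or above stimulated. The standard errors rest on 2 or 3 libraries per group, and a small stimulated share with other changes added stays open. Of the 10 splits of the stimulated libraries 1, the real one with 10765 genes, called any gene (0 at most in the others), and 10 splits are too few for a share under 0.05. The block of activation by TRAIL that the design was built to ask about stays open and untested, as do cell death that spares some cell types and a weaker stimulus in those wells.

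The second pattern is that interferon response genes were higher with TRAIL than in medium (list mean 1.98 ± 0.056). The tables argue against more reads from other cells as the whole cause, since B cell, macrophage and neutrophil markers changed by -0.18 ± 0.047, -0.60 ± 0.062 and -0.92 ± 0.066, and against scaling, since the list was at 2.04 ± 0.043 after it. Endotoxin in the added protein stays open, because genes that endotoxin raises in myeloid cells were higher by 1.16 ± 0.071 (11 of 15 higher, 1 lower, Il12b at -1.85) and no library received a control protein. That list was written after values of several of its genes had been seen, and Ifng from the T cells could raise many of the same genes. A response to TRAIL itself stays open and was not tested.

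The third pattern is that T cell receptor machinery genes were higher in Lck-Cre than in floxed libraries with TRAIL, a call lost at adjusted p = 0.994 with an estimated correlation. A higher share of T cells would raise other T cell genes alike. With lane in the fit, 19 T cell identity genes were higher by 0.73 ± 0.31, leaving a difference of -0.22 ± 0.12 for the machinery list. Markers of B cells (0.09 ± 0.20), neutrophils (-0.27 ± 0.33) and macrophages (-0.06 ± 0.21) did not move beyond their spread. A higher share of T cells thus stays open, since the identity genes rose by no less than the machinery genes. Lane alone would leave no difference within lanes, and the list mean was 0.51 ± 0.20 with lane in the fit (0.82 in lane 2 and 0.28 in lane 4) and 0.37 ± 0.50 without. The mean was larger with lane in the fit than without it and was above 0 in both lanes, which lane alone would not give. Lane is still left open because this mean did not exceed 0.5 of the one without lane by 2 standard errors. That rule was made stricter after the value was seen, and each lane holds 1 Lck-Cre library. Without floxed TRAIL replicate 1 the list median was 0.0033. That fit had no lane term and no floxed TRAIL library on lane 2, so it cannot decide about lane. Protection of T cells by loss of the TRAIL receptor and a different RNA preparation, which the higher Mir6236 reads of both Lck-Cre libraries leave possible, were not tested.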
